A study of Mus musculus with 14 samples.

How the data were processed

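Small RNA was sequenced from the small intestinal epithelium of C57BL/6J mice that carry a Sox9-eGFP transgene, in which green fluorescence follows the activity of the Sox9 gene. Cells were sorted by fluorescence into 4 populations named High, Low, Sublow and Negative, with 3 libraries each, and 2 libraries were made from Non-sorted cells. In this mouse, High cells have been linked to the enteroendocrine lineage, Low cells to crypt stem cells, Sublow cells to transit-amplifying progenitors and Negative cells to differentiated cells. The labels name a TriLink CleanTag kit for library preparation. The labels do not say whether the libraries of a group come from separate animals, so the p-values measure only the spread between these libraries.

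The authors deposited one table of values for 2030 miRNA entries in all 14 libraries, in RPM over the miRNA entries, that is reads scaled so that every library has a total of 1e+06. Of these entries, 534 carry only the name of a mature miRNA and 1496 carry a suffix with a sign and a number, which was read as a sequence whose start is shifted from the annotated position, since the header does not define it. The submitters' processing notes name the genome build mm9, and the aligner and counting settings are not given in the sources used here. No genome coordinates were used, and gene neighbours were taken from the name table of assembly GRCm38.p6. Where a mature miRNA comes from several hairpins, the table lists each hairpin copy as its own entry. In 8 of 23 tested pairs of copies the values differ by at most 5 percent in every library, so a change cannot be assigned to one of these copies.

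The depth of each library was estimated from the steps between its low values, which lie at multiples of the worth of 1 read. It came to 1.89 to 16.4 M reads (M, 1e+06) (median 5.00), and 70.8 to 84.6 percent of the low values (median 79.1) were whole numbers of reads within 0.1 read. The smallest listed value was 0.62 to 5.55, equal to 9.99 to 10.9 reads, so entries with fewer reads appear as 0. A value of 0 therefore means below about 10 reads, not absence, and no fold change is given against a group listed at 0 in all libraries.

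Values were analysed as log2(value + 1), a scale that understates fold changes of entries with low values. Entries with a value of at least 10 in at least 3 libraries were tested, 588 in all (275 at the annotated start, 252 mature names, and 313 shifted). One linear model with the 5 groups was fitted to the 14 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend). Comparisons were any difference among the 4 sorted populations (moderated F test), the 6 pairs of sorted populations, and the mean of the sorted populations against Non-sorted. All tests were two-sided, with Benjamini-Hochberg adjustment over the 588 entries and a threshold of 0.05. Differences are given as first group minus second group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

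The miRNAs to name were set by a rule. For the comparisons with Low, these are up to 10 annotated-start entries with the largest change in each direction among those past the threshold, with a mean of at least 100 in the higher group and library values that do not overlap between the groups, and up to 5 in each direction for the other comparisons. Shifted entries are counted and up to 5 examples by the same rule may be named. Named too are the 5 smallest p-values of the F test, the 10 entries with the largest mean, and any member of 16 miRNA lists. The lists, drawn up from general knowledge, were enteroendocrine and neuroendocrine, HNF-regulated miR-192, miR-194 and miR-215, miR-17-92 and paralogous clusters, let-7 and miR-98, miR-200 epithelial family, miR-34 and miR-449 family, miR-29 and miR-30 families, miR-181 family, miR-15/16 and miR-195/497, stem cell and regeneration linked, the pluripotency clusters miR-290 and miR-302, mesenchymal and smooth muscle, haematopoietic and immune, erythroid, endothelial, and the Dlk1-Dio3 imprinted cluster. miR-1a-3p, miR-99a-5p, miR-100-5p and miR-125b-5p belong both to the stem cell list and to the mesenchymal list, and the first pair of them was tested. A member with several copies was represented by its most abundant copy, and names were matched also in their older form. The 13 lists with at least 3 tested members were tested against the other entries with camera in limma at a preset correlation of 0.01, adjusted over the 13 lists of a comparison, and again with an estimated correlation. Where one count is given for a list, the count adjusted over the list alone is the same, and list counts without a value after median-ratio rescaling did not change with it. The design, the lists, the naming rule and a first set of alternatives were fixed before the data were examined.

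The procedure was tested on simulated data in the layout of the study, with 548 entries past the filter and 200 changed entries. In High vs Low it recovered 18.0 percent of entries changed by 1.5-fold, 55.6 percent of those changed by 2-fold and 81.0 percent of those changed by 4-fold, and 1.02 percent of 98 calls fell on unchanged entries. In a comparison with no changed entry it made 0 calls. In the F test, 4.65 percent of calls fell on unchanged entries. Only less abundant entries were changed, in High alone, and entries were drawn independently, without lane, replicate or carry-over effects. The simulation therefore does not show how many false calls such effects, or a change in a dominant entry such as miR-215-5p, would give.

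The first set of alternatives was pseudocounts of 0.1 and 10, no filter and a filter of 100, median-ratio rescaling (over the 413 entries above 0 in every library), quantile normalization, no trend, a replicate block, a lane term, only single-lane or only combined-lane libraries, only annotated-start entries, only the libraries of the 2 groups compared, an estimated correlation for the lists, and leaving out each library. Alternatives chosen after seeing the data were summing hairpin copies, read-count weights (voom in limma), leaving out sequencing lane L006, only lane L005, only lane L006, and leaving out the 7 libraries that list miR-295-3p. Lane labels divide the libraries unevenly. L005 holds Low replicate 1, Sublow replicates 1 and 3 and Negative replicate 3, and L006 holds Sublow replicate 2, Negative replicates 1 and 2 and both Non-sorted libraries. L008 holds High replicate 3, and High replicates 1 and 2 and Low replicates 2 and 3 carry a combined label that does not give their lanes. High shares no lane label with Sublow or Negative.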

Results

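Crypt cells of the mouse small intestine were separated into subpopulations by Sox9-eGFP fluorescence, and the question was which miRNAs differ between them. The data are 14 small RNA libraries: 3 each of High, Low, Sublow and Negative cells and 2 of Non-sorted cells, at an estimated 1.89 to 16.4 M reads (M, 1e+06). Values are RPM over miRNA entries, given as mean and SD over the libraries of a group, and fold changes are log2 values from limma.

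The sorted populations carried distinct miRNA profiles. Of 588 tested entries, 425 (72.3%) differed among the 4 populations, 233 of them shifted forms. The strongest differences were in miR-215-3p (F = 668, adjusted p = 1.78e-10), miR-194-1-5p, miR-375-3p, miR-182-5p and miR-215-5p (adjusted p = 1.08e-09 each). miR-215 and miR-194, which are under control of hepatocyte nuclear factors in gut epithelium, were lower in High and Low cells than in Negative cells. miR-375, an abundant miRNA of endocrine cells, ran the opposite way. miR-215-5p alone made up 4.04% (SD 0.62) of the summed miRNA values in High, 4.85% (0.44) in Low, 24.3% (0.94) in Sublow, 34.0% (0.50) in Negative and 34.4% (6.48) in Non-sorted cells. Because each library has a fixed total, this share alone lowers the values of other miRNAs in Sublow, Negative and Non-sorted libraries. The counts of higher and lower entries are therefore given also after median-ratio rescaling. This rescaling takes the typical entry as unchanged, an assumption that was not tested and that 425 differing entries of 588 make uncertain. High and Low differ little in the miR-215-5p share, but rescaling still shifted High vs Low by 0.33 on the log2 scale. The 10 most abundant entries held 48.8 to 71.2% of the summed values of a library. They are miR-215-5p, miR-192-5p and a shifted form of it, miR-194-1-5p, miR-375-3p, let-7b-5p, both copies of let-7c-5p, miR-21-5p and miR-26a-2-5p. On the first 3 principal axes, 54.4%, 21.1% and 6.80% of the variance fell. On the second axis, the 7 libraries that list miR-295-3p lay at −33.1 to −6.33 and the other 7 at 0.28 to 22.5. This split runs through each sorted population. Libraries of one group correlated at a Pearson r of 0.835 to 0.987 (median 0.915).

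**Figure D1:**
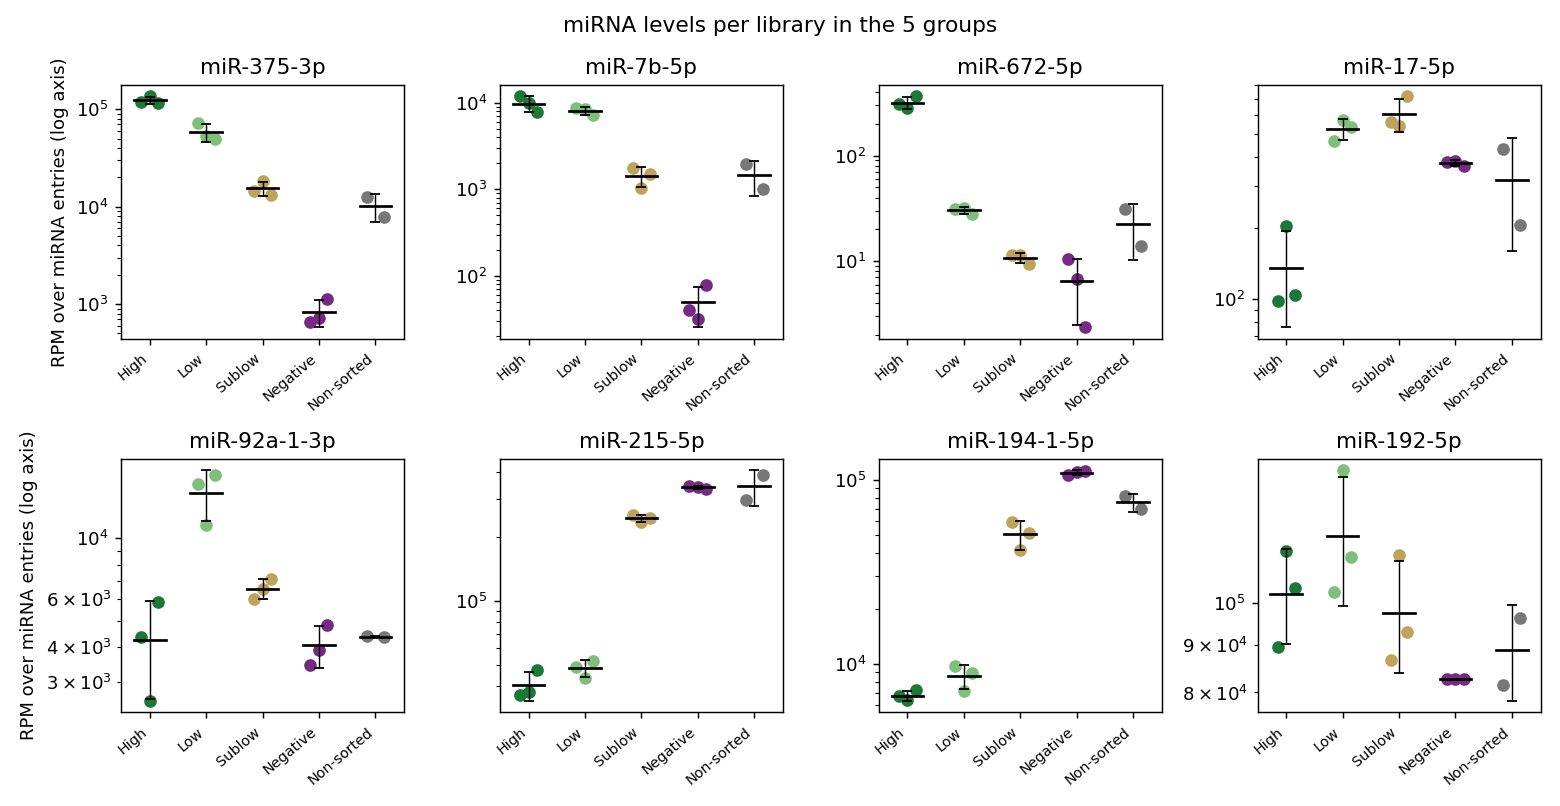
RPM over miRNA entries (log axis) of 8 miRNAs in each library of the 5 groups, with lines for group means and error bars for the SD. The group mean of miR-375-3p runs from 123490 in High to 837 in Negative libraries and miR-194-1-5p from 6746 to 109618, while miR-192-5p stays between 82725 and 118239.

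High cells carried more miR-375, miR-182 and miR-183 than Low cells, miRNAs of endocrine and sensory cells, and less miR-17, miR-221 and miR-222, which are linked to proliferation. miR-375-3p averaged 123490 (SD 10093) in High against 58075 (11881) in Low, 2.13 times as much (log2 fold change 1.10, SE 0.23, adjusted p = 0.00413, and 0.71 between the single-lane libraries, 1 of High on lane L008 and 1 of Low on lane L005). miR-182-5p and miR-183-5p, made from one cluster that is prominent in sensory cells, were 36206 (3107) against 13456 (976) and 3387 (94.0) against 1193 (91.8), at log2 fold changes of 1.43 and 1.51 (adjusted p = 1.39e-06 and 3.44e-06). miR-672-5p was 10.4 times higher in High, 317 (42.3) against 30.5 (2.36) (3.33, SE 0.40, adjusted p = 9.26e-05). On the other side, miR-17-5p was 135 (58.8) in High against 525 (53.4) in Low (−2.03, SE 0.29, adjusted p = 3.57e-04), and miR-222-3p, a repressor of the cell cycle inhibitor Cdkn1b, was 63.0 (16.1) against 316 (45.4) (−2.33, adjusted p = 7.88e-05).

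In High vs Low, 165 entries passed, 47 higher in High and 118 lower. Of these, 89 start at the annotated position, 23 higher and 66 lower. Within the naming rule (a mean of at least 100 in the higher group and no overlap), the largest increases at the annotated start were in miR-672-5p, miR-210-3p (2.92), which is induced by hypoxia, miR-139-3p (1.92), miR-1224-5p (1.79), miR-183-5p, miR-182-5p, miR-340-5p (1.12), miR-375-3p, miR-744-5p (0.98) and miR-429-3p (0.87). miR-1224-5p had adjusted p = 0.0106, 0.167 with pseudocount 0.1 and 0.0533 with a lane term. miR-744-5p had adjusted p = 0.0381, above 0.05 when any of 7 libraries is left out and up to 0.117 without Low replicate 2. By the same rule, the largest decreases were in miR-152-3p (−3.32), miR-222-3p, miR-20a-5p (−2.03), miR-17-5p, miR-92a-1-3p (−1.84), miR-181c-3p (−1.83), miR-92a-2-3p (−1.83), miR-181b-1-5p (−1.79), miR-203-3p (−1.77) and miR-802-5p (−1.72). The other 76 are shifted forms, for example of miR-183-5p (1.71) and miR-203-3p (−1.75).

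Of 11 tested members of the enteroendocrine list, 4 were higher in High, 0 lower and 7 did not pass, with the same counts adjusted over the list alone (median 0.76, adjusted p = 2.61e-04, and adjusted p = 0.134 with an estimated correlation). The 4 were miR-375-3p, miR-182-5p, miR-183-5p and miR-153-3p (2.02, adjusted p = 0.0432, above 0.05 when any of 10 libraries is left out and up to 0.144 without High replicate 2), while miR-7b-5p was 9772 (2021) against 8107 (822) (adjusted p = 0.636). Of 8 miR-200 family members, which maintain epithelial identity, 5 were higher and 0 lower, also adjusted over the list alone (median 0.56, adjusted p = 5.57e-04, and adjusted p = 0.134 with an estimated correlation), among them miR-429-3p and miR-200a-3p (0.76). Of 15 members of the miR-17-92 list, 8 were lower and 0 higher, also adjusted over the list alone (median −1.41, adjusted p = 5.57e-04, and adjusted p = 0.134 with an estimated correlation), among them miR-25-3p (−1.41) and miR-93-5p (−1.67). In the miR-181 family, 4 of 5 were lower and 0 higher, also adjusted over the list alone (median −1.08, adjusted p = 0.0370, and adjusted p = 0.271 with an estimated correlation), with miR-181d-5p at −1.33. Of 9 let-7 members, whose mature forms accumulate in differentiated cells, 6 were lower and 1, let-7e-5p, higher, also adjusted over the list alone (median −0.48, adjusted p = 0.0370, and adjusted p = 0.432 with an estimated correlation). After median-ratio rescaling 3 let-7 members were higher and 2 lower and the call was lost (adjusted p = 0.614), and let-7e-5p, at 0.65 with adjusted p = 0.0465, was above 0.05 when any of 9 libraries was left out, up to 0.147 without Low replicate 3. The let-7 call was also lost without High replicate 2 (adjusted p = 0.155), and the miR-181 call after median-ratio rescaling (0.0521, with 2 members lower) and without High replicate 1, High replicate 2 or Low replicate 2 (0.0604, 0.0709 and 0.0688).

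The other lists gave no call in High vs Low. In the HNF list 1 of 7 was lower, miR-215-3p (−0.56, list adjusted p = 0.160). The stem cell list had 4 of 7 lower and 0 higher (median −1.18, adjusted p = 0.0507, and 0.0494 and 0.0442 without Low replicate 3 and Negative replicate 3), with miR-221-3p at −1.72 and miR-21-5p at −1.18. Of 2 tested members of the miR-34 and miR-449 family, miR-34a-5p was lower, 33.4 (13.9) against 103 (38.6). In the miR-29 and miR-30 families 3 of 9 were lower (adjusted p = 0.425). In the miR-15/16 list 1 was higher and 2 lower of 5, and its median of −0.31, mean of 0.48 and downward test (adjusted p = 0.920) differ in sign. In the haematopoietic list (0 of 6 passed) the median of −0.69 stands against an upward test (adjusted p = 0.920). In the mesenchymal list 1 of 4 was lower, and 2 adjusted over the list alone. No member passed among 8 of the pluripotency clusters, 9 of the Dlk1-Dio3 cluster, 1 erythroid and 1 endothelial. For all these lists except the mesenchymal one, the counts adjusted over the list alone were the same. After median-ratio rescaling the higher and lower counts were 5 and 0 in the enteroendocrine list, 6 and 0 in miR-200, 0 and 7 in miR-17-92, 2 and 0 in miR-29 and miR-30, 1 and 0 in miR-15/16, 1 and 3 in the stem cell list and 0 and 0 in the HNF and mesenchymal lists. Rescaling shifted High vs Low by 0.33 on the log2 scale, and 151 entries then passed, 81 higher and 70 lower (53.6% higher, against 28.5%). With quantile normalization 61 were higher and 80 lower (43.3%).

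**Figure D2:**
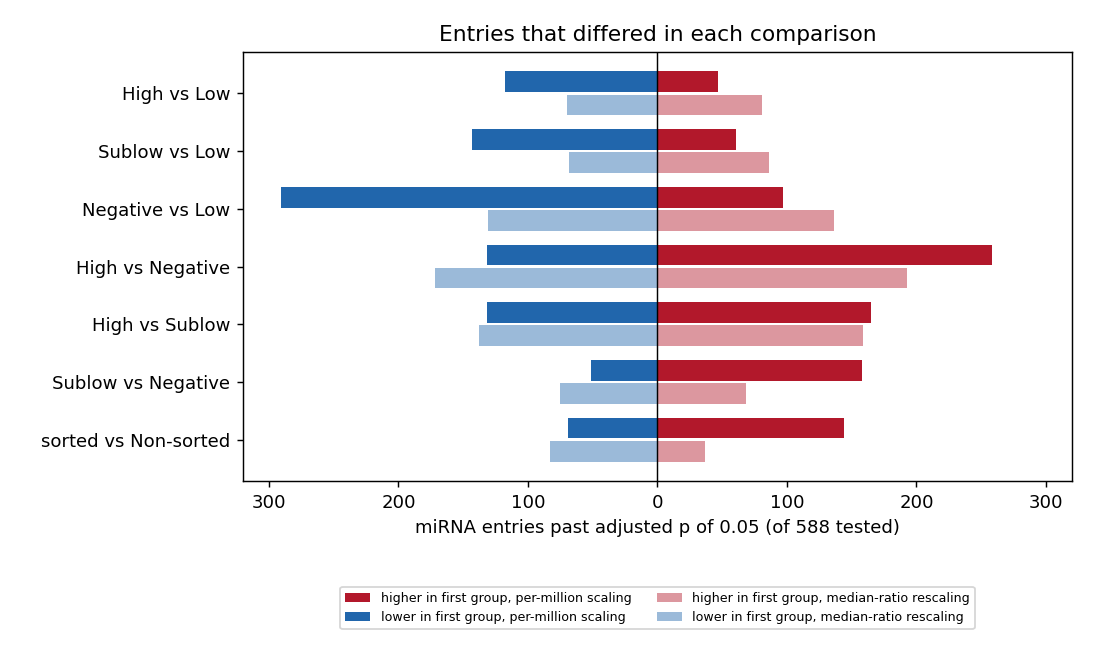
Number of the 588 tested miRNA entries past an adjusted p of 0.05 in each comparison, higher in the first group to the right and lower to the left, for the deposited scaling (dark) and after median-ratio rescaling (pale). In Negative vs Low 97 are higher and 291 lower, and 136 and 131 after rescaling.

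Sublow cells carried several times more miR-194 and miR-215 than Low cells and less of the endocrine miRNAs. miR-215-5p averaged 243442 (SD 9384) in Sublow against 48475 (4446) in Low, 5.02 times as much (log2 fold change 2.33, SE 0.12, adjusted p = 9.19e-08), and miR-194-1-5p 50874 (9033) against 8614 (1306), 5.91 times as much (2.56, SE 0.14, adjusted p = 1.14e-07). miR-7b-5p, which is enriched in neuroendocrine cells, was 1422 (367) against 8107 (822) (−2.54, adjusted p = 1.46e-04), and let-7e-5p 366 (54.2) against 1945 (300.3) (−2.41, adjusted p = 1.17e-05). The transcripts of miR-194-1 and miR-215 are neighbours in the mouse gene table with 0 genes between them. Of the other neighbouring pair, miR-192 and miR-194-2, miR-192-5p was 97542 in Sublow and 118239 in Low (−0.27, adjusted p = 0.128, and 0.12 after median-ratio rescaling) and miR-194-2-3p 481 and 501, while miR-194-2-5p, which has the mature sequence of miR-194-1-5p, rose.

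In Sublow vs Low, 204 entries passed, 61 higher and 143 lower, of which 17 and 87 start at the annotated position. Further increases at the annotated start were in miR-215-3p (2.54), miR-194-1-3p (2.43), miR-5109 (2.06), miR-194-2-5p (1.52), miR-802-5p (1.07), miR-22-3p (0.95), miR-103-2-3p (0.86) and miR-103-1-3p (0.85), the last 2 being copies that cannot be separated. Further decreases were in miR-1224-5p (−4.80), miR-92b-3p (−2.81), miR-7a-2-3p (−2.77), miR-125a-5p (−2.70), miR-181c-3p (−2.65), miR-184-3p (−2.61), miR-99b-5p (−2.58) and miR-181c-5p (−2.17). let-7e, miR-99b and miR-125a, which share one primary transcript, thus fell together.

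Of 11 enteroendocrine members, 10 were lower in Sublow and 0 higher, and 11 lower adjusted over the list alone (mean −1.91, adjusted p = 4.11e-04, and adjusted p = 0.206 with an estimated correlation), among them miR-375-3p (−1.91) and miR-7a-1-5p (−1.73). Of 7 HNF members, 4 were higher and 0 lower, also adjusted over the list alone (median 2.33, adjusted p = 5.93e-05, and adjusted p = 0.0951 with an estimated correlation). Of 5 miR-181 members, 4 were lower, and 5 adjusted over the list alone (median −1.86, adjusted p = 0.00702, and adjusted p = 0.213 with an estimated correlation). Of 9 let-7 members, 6 were lower, and 8 adjusted over the list alone (median −0.31, adjusted p = 0.0373, and adjusted p = 0.625 with an estimated correlation), but after median-ratio rescaling the median was 0.08, 1 was higher and 1 lower, the call was lost (adjusted p = 0.879), and let-7a-1-5p (−0.27) and let-7d-5p (−0.31) turned to 0.12 and 0.083. The let-7 call was also lost without High replicate 3 or Low replicate 2 (adjusted p = 0.0510 and 0.0545). In the stem cell list miR-31-5p, which rises in regenerating crypts, was 12698 (731) against 7087 (650.4) (0.84, adjusted p = 7.47e-04) and miR-21-5p rose too (0.56), while 3 of 7 were lower.

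Without a list call, 2 of 15 miR-17-92 members were lower, miR-25-3p (−0.79) and miR-92a-1-3p (−1.14), 3 of 8 miR-200 members (4 adjusted over the list alone), among them miR-141-3p (−1.48), and 5 of 9 miR-29 and miR-30 members, among them miR-30b-5p (−1.01). miR-10b-5p was lower among 2 of 4 mesenchymal members, at 181 (49.6) against 548 (76.5), and miR-146a-5p was the 1 of 6 haematopoietic members that passed, at 168 (85.8) against 581 (181) (adjusted p = 0.0106, and 0.209 with a lane term). The miR-34 and miR-449, miR-15/16, pluripotency, erythroid, endothelial and Dlk1-Dio3 lists had 0 members past the threshold. Medians were negative and tests upward, all with adjusted p = 0.938 or 0.940, in the miR-17-92, miR-15/16, stem cell and Dlk1-Dio3 lists. After median-ratio rescaling the higher and lower counts were 0 and 6 in the enteroendocrine list, 1 and 2 in miR-17-92, 2 and 1 in miR-200, 1 and 1 in miR-29 and miR-30, 1 and 0 in miR-15/16 and 2 and 1 in the stem cell list. Rescaling shifted Sublow vs Low by 0.40, and 154 entries passed, 86 higher and 68 lower (55.8% higher, against 29.9%), and with quantile normalization 82 and 77 (51.6%). Between the 2 Sublow and 1 Low library of lane L005 miR-215-5p was at 2.33 and miR-375-3p at −2.36. A lane term left 130 calls.

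Negative cells, the dimmest, had less of the endocrine miRNAs than Low cells and more of miR-194 and miR-215. miR-375-3p averaged 837 (SD 256) against 58075 (11881) in Low, 69.4 times lower (log2 fold change −6.14, SE 0.23, adjusted p = 1.84e-09), and miR-7b-5p 50.3 (24.7) against 8107 (822), 161 times lower (−7.40, SE 0.33, adjusted p = 4.51e-09). miR-194-1-5p reached 109618 (3423), 12.7 times its level in Low (3.68, adjusted p = 1.84e-09), and miR-215-5p 340410 (5018), 7.02 times (2.82, adjusted p = 3.10e-09). miR-22-3p rose to 3774 (214) (1.85, adjusted p = 3.92e-07) and miR-203-3p, which promotes differentiation in stratified epithelium, to 2513 (135) (1.17, adjusted p = 5.08e-04). miR-192-5p fell by 0.50 on the log2 scale (adjusted p = 0.0055) and turned to 0.37 (adjusted p = 0.0463) after median-ratio rescaling.

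In Negative vs Low, 388 entries passed, 97 higher and 291 lower, of which 20 and 156 start at the annotated position. Other increases at the annotated start were in miR-5109 (4.02), miR-194-1-3p (3.72), miR-215-3p (3.59), miR-194-2-5p (2.32), miR-1981-5p (1.22) and miR-5115 (3.73, SE 1.09, and 1.63 with adjusted p = 0.426 under a lane term). From replicate 1 to 3, miR-5115 fell in both groups, at 16889, 7308 and 2803 in Negative and 1243, 366 and 326 in Low. Other decreases were in let-7e-5p (−4.90), miR-92b-3p (−5.54), miR-125a-5p (−5.27), miR-99b-5p (−4.53) and miR-139-3p (−4.49). miR-1224-5p (0, 0 and 1.44) and miR-184-3p (0, 0 and 0.94) are listed at 0 in 2 Negative libraries each, as is miR-7a-2-3p.

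All 11 enteroendocrine members were lower in Negative, also adjusted over the list alone (median −4.17, adjusted p = 4.22e-04, and adjusted p = 0.208 with an estimated correlation), and 4 of them are listed at 0 in all Negative libraries (median of the others −4.29). Of 7 HNF members, 4 were higher and 1 lower, also adjusted over the list alone (median 2.82, adjusted p = 4.22e-04, and adjusted p = 0.185 with an estimated correlation). All 9 let-7 members were lower, also adjusted over the list alone (median −1.16, adjusted p = 0.00247, and adjusted p = 0.373 with an estimated correlation), but after median-ratio rescaling 1 was higher and 5 lower (adjusted p = 0.120), with let-7g-5p turning from −0.43 to 0.45 and let-7b-5p from −0.83 to 0.048.

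The other lists of Negative vs Low gave no call. 5 of 15 miR-17-92 members were lower, among them miR-25-3p (−2.21), and after rescaling 1 was higher and 2 lower. 6 of 8 miR-200 members were lower, among them miR-141-3p (−1.65), and 1 after rescaling, with 1 higher and with miR-429-3p turning from −0.65 to 0.23. All 5 miR-181 members were lower (3 after rescaling), led by miR-181c-5p (−3.22) and miR-181d-5p (−3.13). 6 of 9 miR-29 and miR-30 members and 2 of 5 miR-15/16 members were lower, and after rescaling 3 were higher and 1 lower, and 1 higher and 0 lower. In the stem cell list 5 of 7 were lower, among them miR-222-3p (−2.89), and miR-31-5p was higher (1.16). 3 of 4 mesenchymal members were lower, with miR-10b-5p at 52.2 (16.5), 4 of 6 haematopoietic members, with miR-146a-5p at 53.2 (42.3), and 1 of 2 miR-34 and miR-449 members, miR-34c-5p. In the Dlk1-Dio3 list 1 of 9 was lower and 0 adjusted over the list alone, and its median of −1.15 stands against an upward test (adjusted p = 0.645). The pluripotency (median 2.70, adjusted p = 0.0901, and 0.0287 and 0.0169 without Low replicate 2 and Negative replicate 3), erythroid and endothelial lists had 0 members past the threshold. After median-ratio rescaling 6 HNF members were higher and 0 lower, the stem cell list had 2 and 3, and 2 mesenchymal, 3 haematopoietic and 0 Dlk1-Dio3 members were lower. The shift by rescaling was 0.88. 267 entries then passed, 136 higher and 131 lower (50.9% higher, against 25.0%), 7 in the opposite direction, and with quantile normalization 119 and 166 (41.8%). Between the single Negative and Low libraries of lane L005, miR-375-3p was at −5.99 and miR-215-5p at 2.77.

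**Figure D3:**
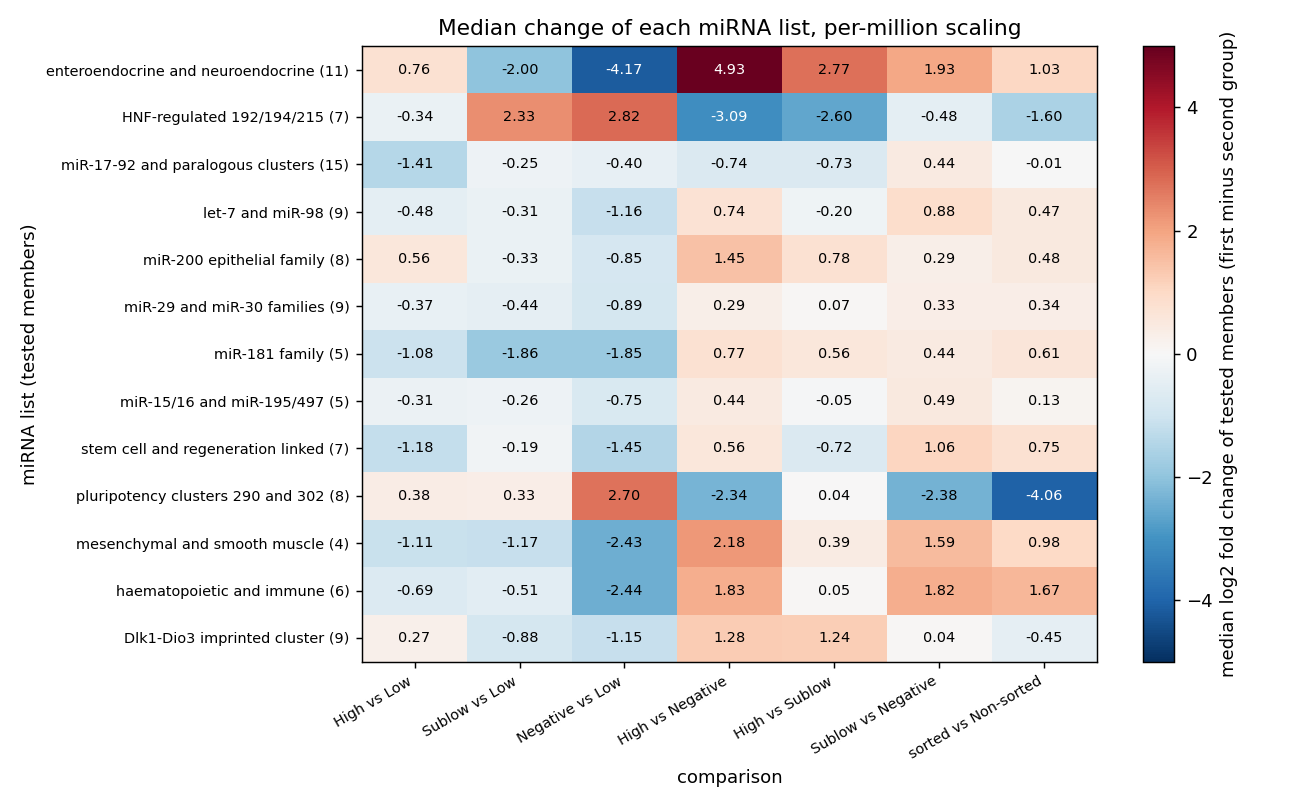
Median log2 fold change of the tested members of 13 miRNA lists (number of members in brackets) in the 7 comparisons, first minus second group, at the deposited scaling. The enteroendocrine list runs from −4.17 in Negative vs Low to 4.93 in High vs Negative, and the let-7 median of −0.31 in Sublow vs Low turns to 0.08 after median-ratio rescaling.

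High and Negative cells, at the ends of the fluorescence scale, parted in the endocrine miRNAs and in the miR-194 and miR-215 group. miR-375-3p was 148 times higher in High (log2 fold change 7.24, adjusted p = 2.20e-10) and miR-7b-5p, at 9772 (2021) against 50.3 (24.7), higher still (7.66, adjusted p = 1.43e-09). miR-1224-5p (947 in High, SD 348), miR-7a-2-3p (455, SD 34.3) and miR-184-3p (308, SD 43.4) were close to or at 0 in Negative libraries. Lower in High were miR-215-3p (−4.16, adjusted p = 9.06e-11), miR-194-1-3p (−4.16), miR-5109 (−4.14), miR-194-1-5p (−4.02) and miR-5115 (−5.73, and −2.25 with adjusted p = 0.419 under a lane term). Of 390 entries that passed, 258 were higher in High and 132 lower, of which 128 and 42 start at the annotated position. Median-ratio rescaling shifted the differences by −0.55 and gave 193 higher and 172 lower of 365 (52.9% higher, against 66.2%). A lane term left 239 calls. No lane label is shared by both groups.

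All 11 enteroendocrine members were higher in High, also adjusted over the list alone (median 4.93, and 5.06 without the 4 listed at 0 in Negative, adjusted p = 4.76e-05, and adjusted p = 0.124 with an estimated correlation). All 8 miR-200 members were higher, also adjusted over the list alone (median 1.45, adjusted p = 0.00844, and adjusted p = 0.138 with an estimated correlation), among them miR-141-3p (1.99) and miR-200a-3p (1.65). 8 of 9 let-7 members were higher, also adjusted over the list alone (median 0.74, adjusted p = 0.0243, and adjusted p = 0.442 with an estimated correlation), and after rescaling 4 were higher and 1 lower and the call was lost (adjusted p = 0.372), with miR-98-5p turned to −0.22. 4 of 7 HNF members were lower, also adjusted over the list alone (median −3.09, adjusted p = 9.32e-04, and adjusted p = 0.124 with an estimated correlation). 7 of 15 miR-17-92 members were lower and 1 higher, also adjusted over the list alone (median −0.74, adjusted p = 0.0418, and adjusted p = 0.442 with an estimated correlation), a call lost without High replicate 1, High replicate 3, Negative replicate 1 or Negative replicate 2 (adjusted p = 0.103, 0.0521, 0.0530 and 0.0579). Without a list call, 3 members of the stem cell list were higher, among them miR-146b-5p (1.48), and 3 lower, among them miR-21-5p (−1.29), and their median of 0.56 (−0.16 without the member listed at 0 in Negative) stands against a downward test. Higher also were 3 miR-181 members (4 adjusted over the list alone) with 1 lower, 4 miR-29 and miR-30 members with 1 lower, 2 miR-15/16 members (3 adjusted over the list alone) with 1 lower, 3 each of the mesenchymal, haematopoietic and Dlk1-Dio3 lists, the latter with miR-127-3p (3.82, 2.36 without Negative replicate 3 and 6.75 without lane L006), and miR-34c-5p (4.65), while miR-34a-5p was lower (−1.60). The pluripotency, erythroid and endothelial lists had 0. After rescaling the higher and lower counts were 0 and 6 in the HNF list, 0 and 8 in miR-17-92, 7 and 0 in miR-200, 2 and 2 in miR-29 and miR-30 and in miR-15/16, 2 and 1 in miR-181 and 2 and 0 in Dlk1-Dio3.

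Between High and Sublow, the endocrine miRNAs and the miR-194 and miR-215 group parted in the same way, at smaller size. miR-1224-5p (log2 fold change 6.59), miR-672-5p (4.75, adjusted p = 1.99e-06), miR-7a-2-3p (3.50), miR-92b-3p (3.49) and miR-125a-5p (3.41) were higher in High, and miR-215-3p (−3.10), miR-194-1-5p (−2.90), miR-194-1-3p (−2.87), miR-802-5p (−2.80) and miR-215-5p (−2.60) lower. All 11 enteroendocrine members were higher, also adjusted over the list alone (median 2.77, adjusted p = 1.06e-05, and adjusted p = 0.0988 with an estimated correlation), as were 7 of 8 miR-200 members (8 adjusted over the list alone, adjusted p = 0.00270, and adjusted p = 0.0988 with an estimated correlation). 4 of 7 HNF members were lower, also adjusted over the list alone (adjusted p = 0.00165, and adjusted p = 0.0988 with an estimated correlation), and 8 of 15 miR-17-92 members (10 adjusted over the list alone, adjusted p = 0.00270, and adjusted p = 0.173 with an estimated correlation), among them miR-17-5p (−2.23). Of the lists without a call, 3 let-7 members were higher and 4 lower (5 adjusted over the list alone), with let-7e-5p at 3.06 and a median of −0.20 against a mean of 0.27. The miR-181 list had 4 higher and 1 lower, the stem cell list 1 and 4, the miR-15/16 list 2 and 2, the miR-29 and miR-30 list 2 and 1 and the miR-34 and miR-449 list 1 and 1. Those with 0 lower were the mesenchymal (1 higher), haematopoietic (2) and Dlk1-Dio3 lists (2), each with 0 adjusted over the list alone. The pluripotency, erythroid and endothelial lists had 0 higher too. In the let-7, miR-15/16, pluripotency and haematopoietic lists the signs of median, mean and test differ. After rescaling the higher and lower counts were 0 and 5 in the HNF list, 3 and 5 in let-7, 3 and 1 in miR-181, 0 and 4 in the stem cell list, 1 and 0 in the haematopoietic and Dlk1-Dio3 lists and 0 and 0 in the mesenchymal list. In all, 297 entries passed, 165 higher and 132 lower, at a shift of −0.07 by rescaling, and a lane term left 159. No lane label is shared by both groups.

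Sublow cells held more of the endocrine miRNAs than Negative cells and less of the miR-194 and miR-215 group. miR-7b-5p (log2 fold change 4.86, adjusted p = 9.27e-07), miR-375-3p (4.23, adjusted p = 3.72e-07), let-7e-5p (2.49), miR-148a-3p (2.08) and miR-7a-1-5p (1.93) were higher in Sublow, and miR-5109 (−1.96), miR-194-1-3p (−1.29), miR-194-1-5p (−1.12), miR-215-3p (−1.05) and miR-22-3p (−0.90) lower. 9 of 11 enteroendocrine members were higher, also adjusted over the list alone (median 1.93, and 2.06 without the 4 listed at 0 in Negative, adjusted p = 7.86e-05, and adjusted p = 0.157 with an estimated correlation), and 8 of 9 let-7 members, also adjusted over the list alone (median 0.88, adjusted p = 1.20e-04, and adjusted p = 0.173 with an estimated correlation). 4 of 7 HNF members were lower, also adjusted over the list alone (adjusted p = 0.00132, and adjusted p = 0.157 with an estimated correlation). Without a call, 5 stem cell members were higher (6, and 1 lower, adjusted over the list alone), with miR-21-5p turning from 0.45 to −0.033 after rescaling. 3 each of the miR-17-92, miR-200, miR-29 and miR-30 and haematopoietic lists were higher, 2 of the miR-181 list, 2 of the mesenchymal list (3 adjusted over the list alone), 1 of the miR-15/16 list (3 adjusted over the list alone) and 1 of the miR-34 and miR-449 family. The pluripotency, erythroid, endothelial and Dlk1-Dio3 lists had 0, though the first was called lower without Sublow replicate 2 or Negative replicate 3 (adjusted p = 0.00975 and 0.00774) and the last without Negative replicate 3 (0.0167). The median of the last, 0.04, stands against a downward test. In all, 209 entries passed, 158 higher and 51 lower, 99 and 9 at the annotated start. After rescaling the higher and lower counts were 8 and 0 in the enteroendocrine list, 0 and 5 in the HNF list, 5 and 0 in let-7, 3 and 1 in the stem cell list, 1 and 0 in miR-17-92, 2 and 0 in miR-200 and the haematopoietic list, 0 and 1 in miR-29 and miR-30, 1 and 1 in miR-181 and 0 and 0 in miR-15/16. Rescaling shifted the differences by −0.48 and gave 68 higher and 75 lower of 143 (47.6% higher, against 75.6%), and quantile normalization 91 and 55 (62.3%). Within lane L005 (2 Sublow, 1 Negative) miR-375-3p was at 3.62 and miR-215-5p at −0.43, and within lane L006 (1 and 2) at 4.73 and −0.55.

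Non-sorted cells carried miR-215 near its level in Negative cells, and miR-194 between its levels in Sublow and Negative cells. The mean of the sorted populations weighs the 4 gates equally, whatever their share among unsorted cells. Cell makeup and sorting are therefore not separated in this comparison. 4 of 7 HNF members were lower in the mean of the sorted populations, also adjusted over the list alone (median −1.60, adjusted p = 1.09e-04, and adjusted p = 0.111 with an estimated correlation), among them miR-215-3p (−2.01) and miR-194-1-5p (−1.67). Higher in sorted cells were 7 of 11 enteroendocrine members (9 adjusted over the list alone, adjusted p = 0.0122, and adjusted p = 0.314 with an estimated correlation), with miR-182-5p at 1.03, and 7 of 9 let-7 members (9 adjusted over the list alone, adjusted p = 0.00589, and adjusted p = 0.314 with an estimated correlation), with let-7e-5p at 1.18. So were 5 of 8 miR-200 members (6 adjusted over the list alone, adjusted p = 0.0313, 0.169 without Non-sorted replicate 1, and adjusted p = 0.314 with an estimated correlation). After rescaling 3 enteroendocrine, 1 let-7 and 2 miR-200 members were still higher, the let-7 and miR-200 calls were lost (adjusted p = 0.394 and 0.365), and miR-98-5p turned to −0.10. The pluripotency list was called lower (median −4.06, adjusted p = 0.0260, and adjusted p = 0.607 with an estimated correlation) with 0 of 8 members past the threshold, a list value of 0.20 under a lane term, and adjusted p = 0.248 after rescaling and 0.121 without Non-sorted replicate 2. Without a call, 3 each of the miR-17-92, miR-29 and miR-30, miR-181 and stem cell lists were higher, 2 each of the mesenchymal and haematopoietic lists and 1 each of the miR-15/16 and miR-34 and miR-449 lists, and none of the Dlk1-Dio3, endothelial and erythroid lists (1 erythroid adjusted over the list alone). After rescaling 0 were higher in miR-17-92, in miR-29 and miR-30 and in miR-15/16, and 1 each in the miR-181, mesenchymal, haematopoietic and stem cell lists. The last had 1 lower. In all 213 entries passed, 144 higher and 69 lower, and 57 and 42 of 99 with a lane term (57.6% higher, against 67.6%). Rescaling shifted the differences by −0.39 and left 37 higher and 83 lower of 120 (30.8% higher), read-count weights gave 78 and 87 (47.3%), and without Non-sorted replicate 2 there were 90, 44 higher and 46 lower. miR-28-5p, the miRNA the naming rule gave, was 331 (47.3) against 229 (34.7) (0.53, adjusted p = 0.0122, 0.195 without Non-sorted replicate 2, and 0.448 after rescaling).

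Several miRNAs from the lists for cells outside the epithelium were measurable at low levels. Which cells they come from was not tested. Of the haematopoietic list, miR-146a-5p was higher, at 432 in High, 581 in Low, 168 in Sublow and 53.2 in Negative libraries. miR-143-3p, abundant in smooth muscle and fibroblasts, averaged 9.26 in High, 38.2 in Low, 18.6 in Sublow and 16.6 in Negative libraries. Erythroid miR-486-5p averaged 33.8, 24.6, 18.0 and 17.9, and endothelial miR-126-5p 11.5, 8.38, 2.69 and 3.12, in the same order. Lymphocyte miR-150-5p followed lanes and the miR-295-3p split more than populations. It is listed at 33.9 to 74.2 in the 4 libraries of lane L005, at 22.6 in High replicate 1 and at 39.2 in Low replicate 3. Of the 7 libraries that list miR-295-3p, only Non-sorted replicate 2 lists miR-150-5p, at 3.07. In all remaining libraries, High replicate 3 included, it is at 0. Lane and the miR-295-3p split cannot be told apart here. miR-155-5p of the haematopoietic list was at 46.7 to 103 in lane L005, 86.8 in Low replicate 3 and at most 42.4 elsewhere. Members of the miR-290 cluster, which marks pluripotent cells, followed lane and replicate number. miR-295-3p is listed at 663 to 839 in the 5 libraries of lane L006, at 928 in High replicate 2 and 395 in Low replicate 2, and at 0 in the other 7 libraries. All 5 replicate 2 libraries thus list it. Of the Dlk1-Dio3 list, miR-379-5p, miR-411-5p and miR-300-3p were highest in the same 7 libraries, miR-379-5p at 19.9 to 31.4 there and at most 11.1 elsewhere. So was miR-106a-5p of the miR-17-92 list (49.7 to 77.3, and at most 37.0). Without these 7 libraries the miR-17-92 list was still called in High vs Low, High vs Negative and High vs Sublow (adjusted p = 1.43e-04, 0.0258 and 0.00181). Without lane L006 it was not called in High vs Negative (0.0667), though its mean relative to the other entries was −1.31, against −1.41 with all libraries.

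**Figure D4:**
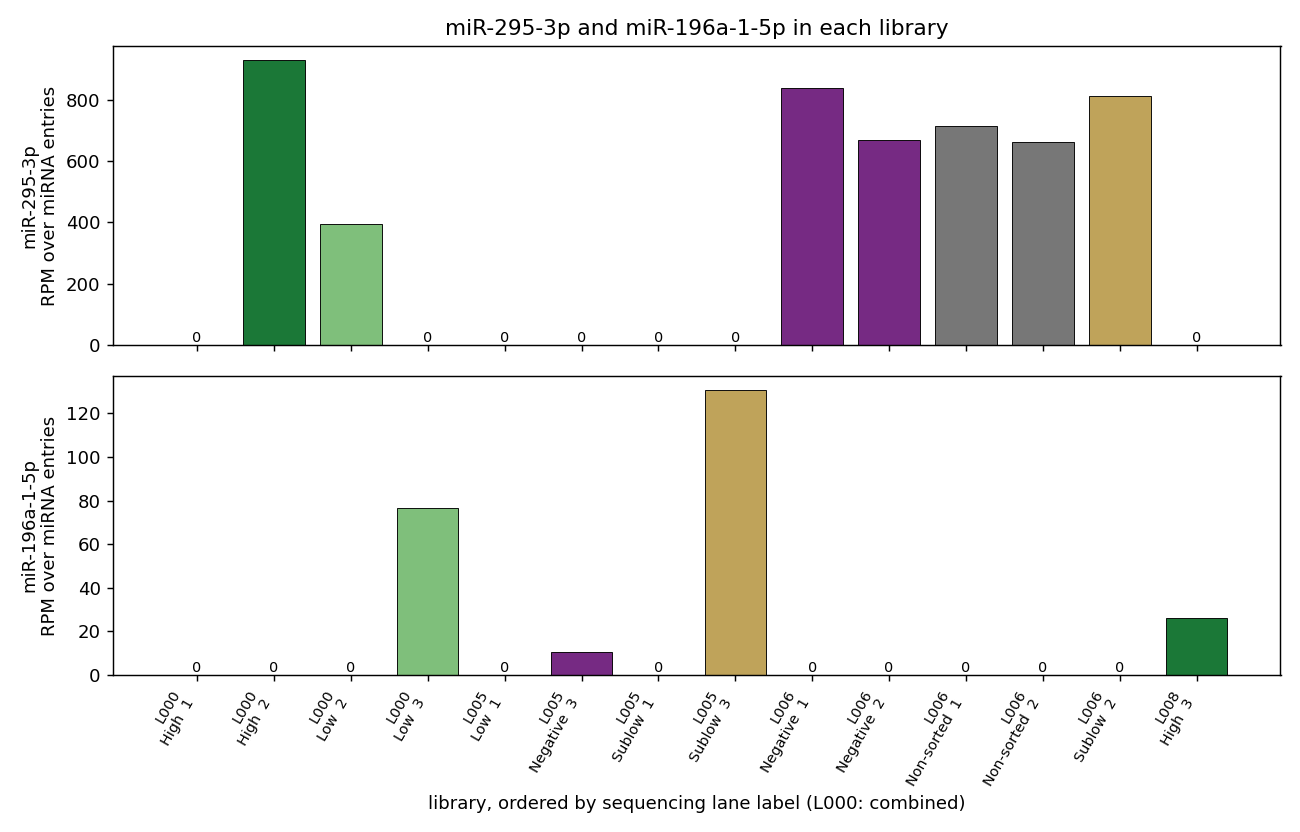
RPM over miRNA entries of miR-295-3p (top) and miR-196a-1-5p (bottom) in each of the 14 libraries, ordered by lane label and coloured by group, with 1 bar per library. miR-295-3p reaches 928 and is 0 in 7 libraries, and miR-196a-1-5p is above 0 only in the replicate 3 libraries of the sorted populations, at 10.5 to 131.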

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

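The alternatives chosen after seeing the data were summed hairpin copies, read-count weights, leaving out lane L006, only lane L005, only lane L006 and leaving out the 7 libraries that list miR-295-3p. Of 13883 values of 464 named results under all alternatives, 12882 kept their direction and stayed past the threshold, 974 kept their direction only and 27 reversed. Of these values 6469 come from leaving out 1 library (279 kept their direction only). Of 464 values each, the direction only was kept by 105 with a lane term (1 reversed), 97 with median-ratio rescaling (17 reversed) and 75 with quantile normalization (9 reversed), and by 103 of 440 in single-lane libraries. Of 2794 values of 91 list results, 2647 stayed on their side of the threshold, 104 lost a call in the same direction and 38 gained one. The other 5 were called lists that reversed. A change of direction in a list without a call was not counted as reversed. Depth limits what can be seen below about 10 reads, where entries are listed as 0. Where no cause is given, the cause was not tested.

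Counts that moved by more than 1.5 times were as follows. With the stricter filter (fewer entries tested) 207 passed for any difference, 100 for High vs Low, 198 for Negative vs Low, 188 for High vs Negative and 170 for High vs Sublow. With annotated-start entries only (fewer tested) these were 191 for any difference, 92 for High vs Low, 105 for Sublow vs Low, 176 for Negative vs Low, 168 for High vs Negative, 149 for High vs Sublow, 108 for Sublow vs Negative and 94 for sorted vs Non-sorted. A lane term left 130 for Sublow vs Low, 239 for High vs Negative, 159 for High vs Sublow and 99 for sorted vs Non-sorted. With single-lane libraries only (fewer libraries) there were 45 for High vs Low (1 library each, on different lanes), 116 for Sublow vs Low and 193 for High vs Sublow, and with combined-lane libraries only 71 for High vs Low. Lane L005 alone (2 Sublow, 1 Low and 1 Negative library, so the spread comes from the 2 Sublow libraries) gave 113 for Sublow vs Low, 232 for Negative vs Low and 93 for Sublow vs Negative, lane L006 alone 119 for the last, libraries without lane L006 126, and those without the 7 miR-295 libraries 129. Median-ratio rescaling gave 120 for sorted vs Non-sorted. The 29 list calls became 46 with no filter, 18 with the stricter filter and 0 with an estimated correlation, where 18 of 91 limma camera tests had an unadjusted p under 0.05.

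Leaving out 1 library gave 379 to 428 for any difference, 125 to 170 for High vs Low, 164 to 214 for Sublow vs Low, 338 to 405 for Negative vs Low, 326 to 388 for High vs Negative, 245 to 308 for High vs Sublow, 178 to 224 for Sublow vs Negative, 90 (without Non-sorted replicate 2) to 220 for sorted vs Non-sorted, and 27 to 33 list calls. Where an alternative left a group with 1 library, it was assumed to vary like the others.

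With a replicate block the counts were 434 for any difference, 177 for High vs Low, 220 for Sublow vs Low, 396 for Negative vs Low, 399 for High vs Negative, 314 for High vs Sublow, 228 for Sublow vs Negative, 190 for sorted vs Non-sorted, and 30 list calls. Of the list calls, let-7 in High vs Low and in Sublow vs Low had adjusted p = 0.0652 and 0.0507 with the block, and miR-181 in Negative vs Low (0.0482) and the pluripotency list in Negative vs Low (0.0344) and in Sublow vs Negative (0.0244) came past the threshold. Of 464 named results 9 were no longer past it. Deviations from the group means correlated over 0.1 in 17 of 26 same-numbered pairs (median 0.33, −0.35 to 0.78, against a median of −0.11 for other numbers), and 11 of 14 libraries correlated best with their own number. Deviations cancel out within a group, so positive values for the same number go with negative values for others. Negative replicate 1 correlated at 0.48, 0.61 and 0.71 with High, Low and Sublow replicate 2. It stood at −0.23, −0.21 and −0.35 with their replicate 1 libraries, and at 0.11 and −0.11 with Non-sorted replicates 1 and 2. Like those High, Low and Sublow replicate 2 libraries, it lists miR-295-3p, which their replicate 1 libraries do not. The correlations therefore do not separate replicate number from the miR-295-3p split. The sample names carry one prefix per replicate number, but the labels do not say whether it stands for an animal, a batch or a day, and not every pair correlated over 0.1, so the numbers were not taken as pairs.

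Reversed log2 values of named results and of called lists were these. The let-7 list in High vs Low (−0.11 relative to the other entries) turned to 0.0055 with pseudocount 0.1, 0.16 in single-lane libraries and 0.072 without the 7 miR-295 libraries, and leaving out 1 library gave −0.20 to 0.10 (without High replicate 2). The pluripotency list in sorted vs Non-sorted turned to 0.20 under a lane term, and the shifted miR-10a-5p_+_1 in High vs Negative to −0.31. Under median-ratio rescaling the values in Sublow vs Low were 0.12 for let-7a-1-5p, 0.083 for let-7d-5p, 0.0039 for miR-200c-3p and 0.044 for miR-30a-5p. In Negative vs Low they were 0.048 for let-7b-5p, 0.45 for let-7g-5p, 0.12 for miR-15a-5p, 0.036 for miR-16-2-5p, 0.37 for miR-192-5p, 0.059 for miR-200b-5p, 0.033 for miR-221-3p, 0.35 for miR-30c-2-5p and 0.23 for miR-429-3p. Further ones were −0.10 for miR-30a-5p and −0.22 for miR-98-5p in High vs Negative, −0.033 for miR-21-5p in Sublow vs Negative and −0.10 for miR-98-5p in sorted vs Non-sorted. Under quantile normalization they were 0.062 for let-7a-1-5p and 0.033 for let-7d-5p in Sublow vs Low, 0.52 for let-7g-5p and 0.18 for miR-200a-3p in Negative vs Low, −0.028 for let-7a-1-5p in High vs Negative, −0.030 for miR-200c-3p and −0.22 for miR-30d-5p in Sublow vs Negative, and −0.032 for let-7d-5p and −0.0036 for miR-200a-3p in sorted vs Non-sorted.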

Other observations

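The counts over other splits of the libraries were planned, and the other tests of this part were chosen after the result was seen. Some miRNAs set one population apart from each of the other 3 sorted ones, in a test that takes the largest of the 3 p-values (limma) and adjusts over the 588 entries. High cells had 31 entries higher and 35 lower than all others (55 and 40 after median-ratio rescaling), 16 and 19 at the annotated start. miR-351-5p averaged 44.4 (SD 6.74) in High and is listed at 0 in the other 11 libraries, and miR-322-5p, from the same X-linked cluster, averaged 14.3 (2.44) in High and 0.73, 0 and 0 in Low, Sublow and Negative. Both arms of miR-210 were highest in High. Lower in High than in each other population were miR-378-3p, 4161 (364) against 10426, 18731 and 19736 (adjusted p = 6.35e-05), and miR-107-3p, 232 against 591, 693 and 514.5. These miRNAs were picked after their values were seen.

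Negative cells had 48 entries higher and 117 lower than all others (65 and 46 after rescaling), and Low cells 5 higher and 1 lower (1 and 3). The annotated-start entries of Low were let-7i-5p at 17120 (2128), miR-25-3p at 7958 (624), miR-181d-5p at 1547 (218) and miR-181c-3p at 102, which were highest there, and miR-22-3p, lowest at 1053 (164). Of these, miR-181d-5p and miR-22-3p stayed past the threshold after rescaling. Sublow cells had 0 and 0 under both scalings (at an unadjusted p under 0.05, 5 higher and 0 lower, and 0 and 4 after rescaling), and the Sublow mean lay between the Low and Negative means for 461 of 588 entries. miR-191-5p fell to 4677 (947) in Negative from 17039, 19798 and 12712 in High, Low and Sublow (adjusted p = 1.82e-05), and miR-148a-3p to 1278 (355) from 3049, 8441 and 5400 (adjusted p = 9.01e-04).

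All 11 tested enteroendocrine miRNAs were lower in Sublow and in Negative than in High, and 4 of them lower in Low too, and sorting impurity is a candidate explanation. If High cells carried into the Low gate were the sole source, all 11 tested members would keep one Low to High ratio. The ratios ran from 22.3% (miR-153-3p, SE 0.67 on the log2 scale) to 85.6% (miR-7a-1-5p), with miR-375-3p at 47.0% and miR-183-5p at 35.2%. The heterogeneity p was 1.01e-06 (Q = 46.8, 10 degrees of freedom). It rests mostly on miR-182-5p and miR-183-5p, from one cluster, with SEs of 0.096 and 0.11 against 0.23 to 0.69 for the others. Whether the others keep one ratio was not tested, so carry-over of High cells stays open for them. If Sublow were a mix of Low and Negative cells at one share, the share read from 61 entries higher in Low and from 12 entries higher in Negative would be equal. The means were 28.6% and 57.4%, a difference of 28.8 percentage points (19.9 to 38.6 in the 3 libraries, SE 7.15 to 9.37). The SE treats entries as independent, although both sets hold copies or arms of one miRNA, and is thus likely too small. Single entries higher in Negative gave shares from 1.85% (miR-802-5p) to 82.0% (miR-5115), so a mix at one share is not settled. Also open are a mix of more than these cells at several shares and a graded level within the cells.

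The miR-290 cluster was listed in 7 libraries of several groups. Expression by one gate is argued against, since 0 of the 4 sorted populations list miR-295-3p in all 3 libraries. All 5 replicate 2 libraries list it, but a shared origin of these as the only source is argued against, since 2 libraries of other numbers list it at no less than the lowest replicate 2 value. Reads carried over from another library on lane L006 and a source such as a reagent cannot be told apart. 5 of 5 libraries of that lane and 0 of 5 of lanes L005 and L008 list it, but this layout was seen first, and the lanes of the 2 combined-lane libraries that list it are not given. 14 of 14 proportions of 7 cluster members to miR-295-3p in these 2 libraries lay within 2-fold of the lane L006 mean, as any single source would give.

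miR-196a-1-5p was listed in the replicate 3 library of all 4 sorted populations (26.2, 76.5, 131 and 10.5 from High to Negative) and at 0 in the other 10 libraries, and miR-10a-5p was highest in replicate 3 in 4 of 4 populations. Both belong to Hox gene clusters, which differ in activity along the gut. The other copy, miR-196a-2-5p, was at 35.7, 101, 160 and 16.2 in replicate 3 from High to Negative. It was also listed at 1.60 in High replicate 1 and 0.66 in Sublow replicate 1. Carry-over within a lane is argued against, since the highest value in lane L005 was 66.0 times the level at which the lane's libraries at 0 would list it, and so is low depth, since the deepest library at 0 lists values down to 1.21% of the median replicate 3 value. The sample names of these 4 libraries begin with a prefix that no other library carries and whose meaning is not given. A shared origin of the replicate 3 libraries, such as an animal or a gut segment, may be the source but cannot be told apart from other causes, since miR-10b-5p was highest in replicate 3 in only 1 of 4 populations and the labels name no animal or segment.

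Other splits of the same libraries tested the counts. For each pair of populations the 10 splits are too few for a share under 0.05. The real split and the highest other gave 165 and 1 entries for High vs Low, 204 and 0 for Sublow vs Low, 388 and 0 for Negative vs Low, 390 and 0 for High vs Negative, 297 and 0 for High vs Sublow and 209 and 4 for Sublow vs Negative. The split with 4 follows lanes L005 and L006 and also which libraries list miR-295-3p, and these libraries do not separate them. In each pair, 1 split, the real one, reached the real count. For any difference among the 4 populations, 1 of 100 splits, the real one, reached 425 entries and the highest other gave 217. This is the smallest share that 100 splits can give, and the splits ignore lane and replicate number. A random grouping of the libraries is argued against but not excluded. For the list calls over the 6 pairs, 8 of 100 splits reached the real 24 and the highest gave 29, so chance is not excluded.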
